A study of Mus musculus with 2 samples.

How the data were processed

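Each of the 2 libraries came from total RNA of pooled whole stomachs of B6NCrl mouse embryos at day 15.5, with embryos of both sexes in each pool, RNA extraction with a mirVana kit, a size fraction above 200 nucleotides, 10 ng of input and added ERCC spike-ins, per the labels. The authors deposited a gene table and a transcript table for each library, made from transcriptome alignments to mm10 with annotation M4, per the text file deposited beside them. The aligner, the quantification program, their versions and the strand setting were not given in the sources used here. The protocol link in the labels names a manual of a low-input cDNA kit, while the labels call the molecule total RNA, and how far unpolyadenylated RNA was captured was not stated. Since the strand setting is not known, reads of a gene and of an antisense neighbour cannot be told apart.

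Per the file headers, the tables give an expected count for each gene and transcript, with reads that match several features divided among them by the authors' quantification. They also give TPM and FPKM, which the authors scaled by effective length and by library, with a posterior-mean version of each unit. In the deposited transcript tables the share of a gene's TPM on each transcript is given in percent. The effective length was the length minus 99 bases for long features. TPM was computed by the authors over all features, spike-ins included, and spike-ins took 4.01% of the TPM in replicate 1 and 6.51% in replicate 2.

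The tables held 43346 Ensembl genes and 129984 transcripts, 96 ERCC sequences, a phiX sequence with 0 counts and features with numeric IDs that carried 86 and 85 counts. Gene symbols, gene types and mm10 coordinates came from GENCODE M21, the same genome build, matched by gene identifier without its version. Of the genes 42462 (98.0%) matched, and the unmatched ones, which took 0.229% and 0.195% of the counts, were kept in all counts of genes but are not named. Spike-ins, phiX and numeric IDs were left out of library sizes and tests. Counts with a fraction made up 29.9% and 28.4% of the genes with counts, at a tolerance of 0.005.

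A gene was called detected at 1 TPM or more in both libraries. Gene lists for stomach cell types, neighbouring organs, pathways and RNA classes (46 lists), the tests and the alternatives, apart from those named below as added, were fixed before the data were examined. A list's level was described by its median TPM in each library and by the percentile of its median log2(TPM + 0.1) among 10000 random lists of protein-coding genes. The ratio of list medians was given as the mean and SD of both libraries' log2 ratios (n = 2), without a test, since no exact test on 2 values can reach significance. Expected counts were rounded to whole numbers for all tests. Library sizes came from TMM factors over the 20918 genes with at least 10 counts in the sum, and the biological coefficient of variation from the common dispersion of an intercept-only fit in edgeR. Genes were compared between the libraries by a two-sided exact binomial test on the counts of both, adjusted by the Benjamini-Hochberg method, and called at an adjusted p below 0.05 and an absolute log2 ratio of at least 1. Ratios used a prior count of 0.5. A fold against 0 counts was computed against a floor of 3 counts in that library. The shift of a list was its median log2 ratio over members with at least 20 counts in the sum, placed among 10000 random lists matched on expression (each member replaced by 1 of its 200 nearest genes) for the lists with at least 4 such members. The bound used for lists, the central 95% of random lists, was set with the data at hand. Isoform shares were compared for genes of the tissue lists with at least 100 counts in each library.

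The named genes followed a rule fixed in advance: the 15 genes with the highest mean TPM outside mitochondrial, ribosomal protein, spike-in and small RNA genes; the 3 highest detected members of each list and its members below 1 TPM; the 8 genes with the largest ratio in each direction among called genes averaging at least 100 counts; 12 regulators and sex-linked genes; and the 5 genes with the largest isoform change. List members that were called different are also named, after their values were seen. Some genes that the rule would name are not reported here. The list of 14 erythroid genes had 13 matches, because the symbol Ahsp was not matched.

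Alternatives comprised other detection thresholds, FPKM, CPM and posterior-mean values, another pseudocount, each library left out, DESeq2 size factors, library totals and spike-in sizes, other count minimums, the edgeR exact test with the common dispersion, means over members, and transcript tables summed to genes. Restrictions to whole counts or protein-coding genes, and the forestomach ratio without its 3 highest members, were added after the data were seen. Parents of processed pseudogenes were found by aligning M21 transcripts with minimap2.

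The comparison was tested on simulated counts drawn from the real genes and library sizes with 200 genes changed. With a spread of 10% between libraries, 53% of the 2-fold and 100% of the 4-fold changes were recovered at the minimum ratio, and 0.328% of unchanged genes were called, against 35.4% without that minimum. Of unchanged random lists 6% lay outside the central 95%, and 94% of lists moved by 0.3 on the log2 scale were found. The libraries themselves gave an estimate of 19.7%, so these rates may not hold for them. Random lists were drawn gene by gene and carry no shared variation of list members. In the libraries 20 of the 41 lists with a percentile lay outside the central 95%. The dispersion estimate returned 10.0% with no gene changed and 13.3% with 200 genes changed, so genes that differ raise it. It came from the same libraries that the edgeR exact test compares, and a call kept or lost in that test is not independent evidence on a gene. Software was R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and minimap2 2.31.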

Results

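Total RNA was sequenced from whole stomachs of mouse embryos (strain B6NCrl) at embryonic day 15.5, when the organ consists of a squamous forestomach and a glandular hindstomach surrounded by mesenchyme. The series holds 1 group with 2 biological replicates, each a pool of embryos of both sexes. Replicate 1 pooled 78 embryos and replicate 2 pooled 62. The tables held 44038879 expected counts for replicate 1 and 45625704 for replicate 2, of which 43209506 and 44257493 lay on genes. Externally added ERCC spike-in RNAs took 1.88% and 2.999% of the counts. There is no second condition, so the data answer which genes were expressed in the dissected pools, and how far the 2 pools differed. Genes of adjoining organs were also found, so a gene's level in a pool does not show that stomach cells expressed it. Errors are SDs over the 2 libraries (n = 2). The tables record no molecular identifiers, so reads from PCR copies are not independent, and all intervals and floors cover counting error only.

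The dissected pools expressed 15558 genes at 1 TPM (a length-corrected transcript abundance) or more in both libraries, 13846 of them protein-coding. In both libraries 1560 genes reached 100 TPM. Adult-type globin genes were among the most abundant, leaving aside mitochondrial, ribosomal protein and small RNA genes. Hba-a2 was highest, at 17909.75 TPM in replicate 1 and 10052.75 TPM in replicate 2, and the other globin genes among the top 15 were Hbb-bs (6820 ± 2459 TPM), Hba-a1 (5798 ± 2695 TPM) and Hbb-bt (5285 ± 1984 TPM). The remaining top 15 included the nuclear RNA Malat1 (5091 ± 284 TPM), the cytoskeletal genes Actb (4954 ± 263 TPM) and Tmsb4x (4041 ± 89.7 TPM), Ppia (4429 ± 365 TPM), the ferritin gene Ftl1 (3911 ± 27.2 TPM) and the translation factor Eef1a1 (3624 ± 124 TPM). Pnliprp1, a lipase-related gene of the exocrine pancreas, was at 3213 ± 826 TPM. Gm28437 (8256 ± 396 TPM), Gm42418 (4467 ± 617 TPM), Gm10123 (4064 ± 104 TPM) and Gm29216 (3603 ± 972 TPM) completed the 15. The values of Gm28437, Gm10123 and Gm29216, all annotated as pseudogenes, and of the near-identical globin copies are uncertain, because such genes can share reads. The 10 most abundant genes took 4.97% and 4.53% of the counts.

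Squamous and glandular epithelial genes were both abundant. All 13 forestomach squamous genes were detected, with a median of 137 TPM in replicate 1 and 74.3 TPM in replicate 2, and Krt15 (829.28 and 568.8 TPM), Krt4 (768.5 and 317.99 TPM) and Krt13 (639.2 and 323.92 TPM) led them. All 17 genes of glandular and general gut epithelium were detected too, with medians of 27.5 and 35.5 TPM, and the simple-epithelium keratins Krt8 (821.92 and 824.91 TPM), Krt19 (734.18 and 651.28 TPM) and Krt18 (377.17 and 428.79 TPM) were highest. The log2 ratio of the forestomach to the glandular median was 1.69 ± 0.88, but it was -0.055 from counts scaled to library size (CPM) without a length correction, so the order of these lists depended on the unit. Sox2, a regulator of foregut epithelium (ENSMUSG00000074637.6; mm10 chromosome 3, 34650405 to 34652461), was at 9.57 ± 1.29 TPM. Trp63, the master regulator of stratified epithelium (ENSMUSG00000022510.10; chromosome 16, 25683763 to 25892102), was at 23.3 ± 6.21 TPM. Gata4, a glandular hindstomach regulator (ENSMUSG00000021944.11; chromosome 14, 63198922 to 63271692), was at 36.7 ± 10.7 TPM.

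Genes of differentiated gastric cells were present at low to moderate levels. Whether these transcripts came from the stomach or from adjoining organs was not tested. The gastric mucous list had medians of 4.26 and 3.12 TPM with 8 of 11 members detected, led by Tff1 (163.54 and 123.95 TPM), Psca (158.93 and 38.78 TPM) and Muc1 (53.4 and 72.85 TPM). Aqp5 was below 1 TPM in both libraries. All 10 parietal cell genes were detected at medians of 5.37 and 5.57 TPM, led by Clic6 (31.57 and 35.77 TPM), and the proton pump subunit Atp4b was at 21.23 and 11.29 TPM. Of 6 chief cell genes 4 were detected, led by the pepsinogens Pgc (58.8 and 42.48 TPM) and Pga5 (48.33 and 22.82 TPM) and by Bhlha15 (17.87 and 27.87 TPM), while Chia1 and Lipf were below 1 TPM. The gut endocrine list had medians of 4.67 and 7.04 TPM, with 11 of 14 members detected. The ghrelin gene Ghrl (39.88 and 39.33 TPM), Chga (20.04 and 23.3 TPM) and Chgb (18.4 and 22.93 TPM) led it, and Insm1 and Tph1 were among the members below 1 TPM. The log2 ratio to the gut endocrine median was -0.64 ± 0.72 for mucous, -0.07 ± 0.37 for parietal and 0.96 ± 0.28 for chief cell genes. The mucous and parietal ratios were smaller than the spread between the libraries. The chief median fell in a gap between members. Above Gif (3.27 and 1.17 TPM) the next was Bhlha15 (17.87 TPM) in replicate 1 and Pga5 (22.82 TPM) in replicate 2. The SD of the chief ratio therefore does not show how far it depends on single members. From CPM all 3 ratios were positive, at 1.64, 1.62 and 1.99.

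The stomach wall gave some of the strongest signals. All 15 genes of gastric and pyloric mesenchyme were detected (medians 24.3 and 34.7 TPM), led by Tcf21 (174.15 and 178.55 TPM), Barx1 and Sfrp2 (121.61 and 103.9 TPM). Barx1, a homeobox gene of stomach mesenchyme (ENSMUSG00000021381.4, chromosome 13, 48662998 to 48666507), was at 154 ± 17.2 TPM. The pyloric sphincter regulator Nkx2-5 (chromosome 17, 26838664 to 26845009) was at 10.0 ± 3.59 TPM. The glandular to mesenchyme log2 ratio was 0.10 ± 0.10, and 0.57 from CPM. All 12 smooth muscle genes were detected (medians 118 and 132 TPM), with Acta2 at 1613.04 and 1607.49 TPM, Actg2 at 1060.48 and 1096.19 TPM and Tpm2 at 651.77 and 682.11 TPM. All 12 genes of fibroblasts and extracellular matrix were detected (medians 262 and 245 TPM), with Col3a1 at 1626.94 and 1673.05 TPM, Col1a1 at 1128.42 and 1188.94 TPM and Col1a2 at 608.72 and 617.74 TPM. Of 20 enteric nervous system genes 19 were detected (medians 14.3 and 13.5 TPM), led by Ednrb (76.11 and 82.16 TPM), Uchl1 (60.56 and 62.52 TPM) and Stmn2 (58.81 and 53.44 TPM), and Chat was below 1 TPM. Markers of interstitial cells of Cajal, the pacemaker cells of gut muscle, had medians of 27.1 and 33.6 TPM over 4 genes, led by Ano1 (38.44 and 38.94 TPM), Kit (28.38 and 35.65 TPM) and Etv1 (25.89 and 31.62 TPM). All 8 mesothelial genes (medians 23.1 and 20.5 TPM, led by Aldh1a2, Upk3b and Upk1b) and all 14 endothelial genes (medians 16.1 and 18.2 TPM, led by Egfl7, Eng and Pecam1) were detected.

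Genes of organs that adjoin the stomach were also found. The exocrine pancreas list had the highest median of all tissue lists (301 and 329 TPM), with Pnliprp1 and Ctrb1 (2663.94 and 3322.63 TPM) on top, and only Pnlip below 1 TPM. The median member is Prss1, whose level is uncertain because it shares reads with other trypsin genes. The endocrine pancreas list had medians of 33.9 and 37.1 TPM, with the insulin gene Ins2 at 433.43 and 492.53 TPM, Gcg at 75.53 and 133.3 TPM and Iapp at 84.71 and 96.84 TPM, and Mafa below 1 TPM. Pdx1, expressed in pancreas, duodenum and distal stomach (chromosome 5, 147269959 to 147275848), was at 5.34 ± 1.15 TPM. Liver genes had medians of 40.4 and 21.02 TPM, led by Afp (497.36 and 202.86 TPM), Apoa2 (428.63 and 128.07 TPM) and Trf (390.21 and 159.51 TPM). Intestinal genes had medians of 13.7 and 17.5 TPM, led by Fabp1 (410.1 and 479.62 TPM), Lgals4 (281.17 and 383.31 TPM) and Fabp2 (88.31 and 99.54 TPM), with Sis among the members below 1 TPM and the intestinal regulator Cdx2 at 7.30 ± 0.919 TPM. The 3 spleen genes had medians of 4.48 and 5.32 TPM, with Nkx2-3 at 25.73 and 21.4 TPM, Tlx1 at 4.48 and 5.32 TPM and Spic at 1.67 and 1.02 TPM. Skeletal and cardiac muscle genes had medians of 2.64 and 5.36 TPM, led by Acta1 (15.13 and 39.09 TPM), Myl7 (20.65 and 25.02 TPM) and Tnnt2 (15.27 and 21.05 TPM), with Myh6 below 1 TPM.

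Blood and immune genes were dominated by red cells and macrophages. The 13 matched erythroid genes were all detected (medians 56.4 and 50.4 TPM). All 12 macrophage and myeloid genes were detected (medians 23.7 and 22.5 TPM), led by Lyz2 (283.49 and 246.14 TPM), Tyrobp (69.17 and 58.4 TPM) and Fcer1g (67.27 and 59.15 TPM). Of 8 lymphoid genes only Cd3e (1.14 and 1.88 TPM) was detected in both libraries (median 0.175 TPM), and Il7r, Cd3d, Rag1, Cd8a and Ms4a1 were among the members below 1 TPM in both. Lung genes had medians of 0.090 and 0.060 TPM, with only Sftpc (5.28 and 3.48 TPM) detected and the lung regulator Nkx2-1 at 6 and 4 counts. Adrenal and gonadal genes had medians of 0.480 and 0.485 TPM, with Cyp11a1 (4.45 and 3.43 TPM) and Star (1.43 and 1.25 TPM) detected. Genes of retina and lens (medians 0.070 and 0.050 TPM) and of the germ line (0.055 and 0.060 TPM) served as silent controls, and of these 22 genes only Zp3 (1.38 and 1.34 TPM) was detected in both libraries.

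**Figure D1:**
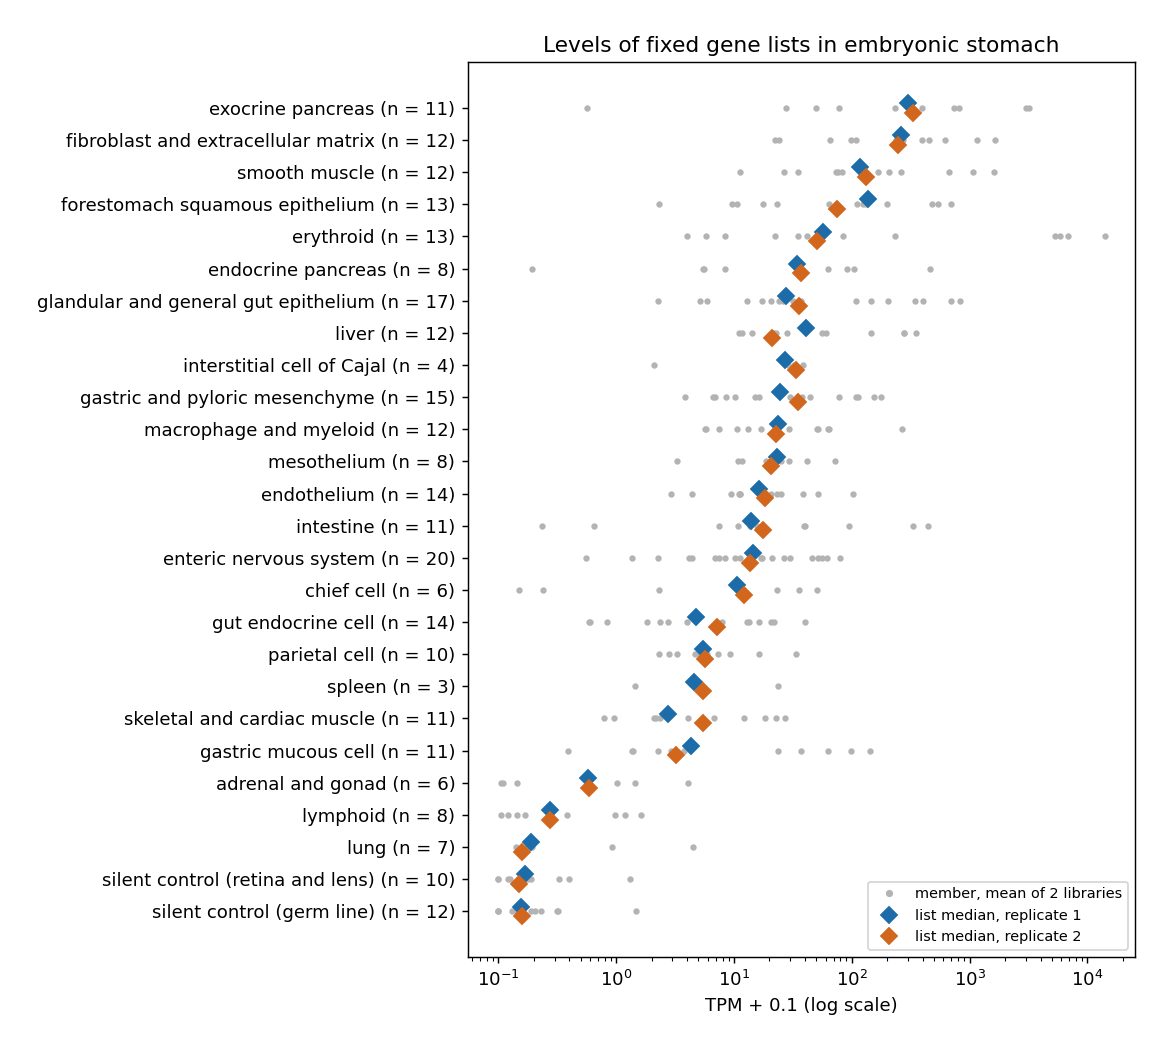
Levels of the fixed tissue gene lists in both libraries. The horizontal axis is TPM + 0.1 on a log scale. Diamonds are list medians of replicate 1 (blue) and replicate 2 (orange), and grey points are members as means of both libraries. Exocrine pancreas (301 and 329 TPM) lies on top and the silent germ line controls (0.055 and 0.060 TPM) at the bottom.

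Signalling genes were expressed throughout. All 12 hedgehog pathway genes were detected (medians 12.9 and 13.0 TPM), led by Gas1, Smo and Ihh, and of the ligands Ihh (chromosome 1, 74945315 to 74951672) was at 22.6 ± 3.81 TPM and Shh (chromosome 5, 28456815 to 28467256) at 6.35 ± 0.247 TPM. Of 16 Wnt pathway genes 15 were detected (medians 5.80 and 5.39 TPM), led by Dkk3, Wnt5a and Lgr4, with Lef1 below 1 TPM. All 14 BMP pathway genes (median 6.87 TPM in both libraries, led by Id2, Id3 and Id1), all 12 Notch pathway genes (medians 11.0 and 12.8 TPM, led by Hes1, Notch2 and Jag1) and all 15 genes of retinoic acid and FGF signalling (medians 27.8 and 24.3 TPM, led by Fgfr2 and Aldh1a2) were detected. The 20 cell cycle genes had medians of 132 and 135 TPM, with Cdk1 at 365.51 and 331.37 TPM and Birc5 at 240.58 and 251.31 TPM. The 24 imprinted genes had medians of 104 and 114 TPM, led by Gnas (1319.71 and 1294.04 TPM), H19 (966.4 and 830.36 TPM) and Igf2 (813.85 and 779.7 TPM). Hypoxia and glycolysis genes (medians 79.2 and 80.2 TPM) were led by Ldha, and immediate early and stress genes (medians 13.7 and 11.8 TPM) by Jun, with Hspa1b and Fosb below 1 TPM. The 8 housekeeping genes had medians of 995 and 1196 TPM.

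Among RNA classes, cytosolic ribosomal protein genes had medians of 630 and 701 TPM and 81 of 84 were detected. Polyadenylated histone variants had medians of 402 and 429 TPM, led by H3f3a, H3f3b and H2afz. Replication-dependent histones, whose mRNAs end without a poly(A) tail, had medians of 7.17 and 4.74 TPM, a log2 ratio of -6.13 ± 0.48 to the variants, although Hist1h2ap alone reached 3147.79 and 2532.37 TPM. Members of this family share reads and are uncertain singly. Summed over members, replication-dependent histones held 4688.65 and 3866.65 TPM and the polyadenylated variants 5099.51 and 5486.03 TPM. The ratio of medians therefore does not describe the total levels of the 2 classes. Structured noncoding RNAs had medians of 64.8 and 49.4 TPM, with the signal recognition particle RNAs Rn7s2 at 13739.98 and 13115.82 TPM and Rn7s1 at 13739.01 and 13115.82 TPM, while Terc and Rny3 were below 1 TPM. Of 37 mitochondrially encoded genes 15 were detected, all of them protein-coding or ribosomal RNA genes, and 22 were below 1 TPM. These 22 were all tRNA genes, with 0 counts in both libraries. The mitochondrially encoded genes took 1.91% and 1.68% of the counts. The mitochondrial tRNAs and Rny3, which also had 0 counts, are shorter than the RNA size fraction taken for the libraries. Their values therefore do not show whether they were expressed. Xist, the X-inactivation RNA transcribed in females, was at 32.8 ± 4.00 TPM and the Y-linked Ddx3y at 13.9 ± 0.849 TPM, and each pool held transcripts of both. The 6 sex-linked genes had medians of 10.3 and 9.67 TPM.

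Each Hox cluster had detected members. In the HoxA cluster 8 of 11 genes were detected, led by Hoxa5 (16.23 and 16.43 TPM), Hoxa7 (12.35 and 7.5 TPM) and Hoxa2 (7.58 and 10.17 TPM). In HoxB 6 of 10 were detected, led by Hoxb2 (16.67 and 17.11 TPM) and Hoxb5 (14.42 and 14.62 TPM), and in HoxC 4 of 9, led by Hoxc4 (14.23 and 13.23 TPM) and Hoxc5 (13.18 and 11.05 TPM). In HoxD only Hoxd3 (12.97 and 11.68 TPM) and Hoxd8 (2.63 and 1.59 TPM) of 9 genes reached 1 TPM in both libraries. The 13th-position genes Hoxa13, Hoxb13, Hoxc13 and Hoxd13 were at or below 0.12 TPM.

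**Figure D2:**
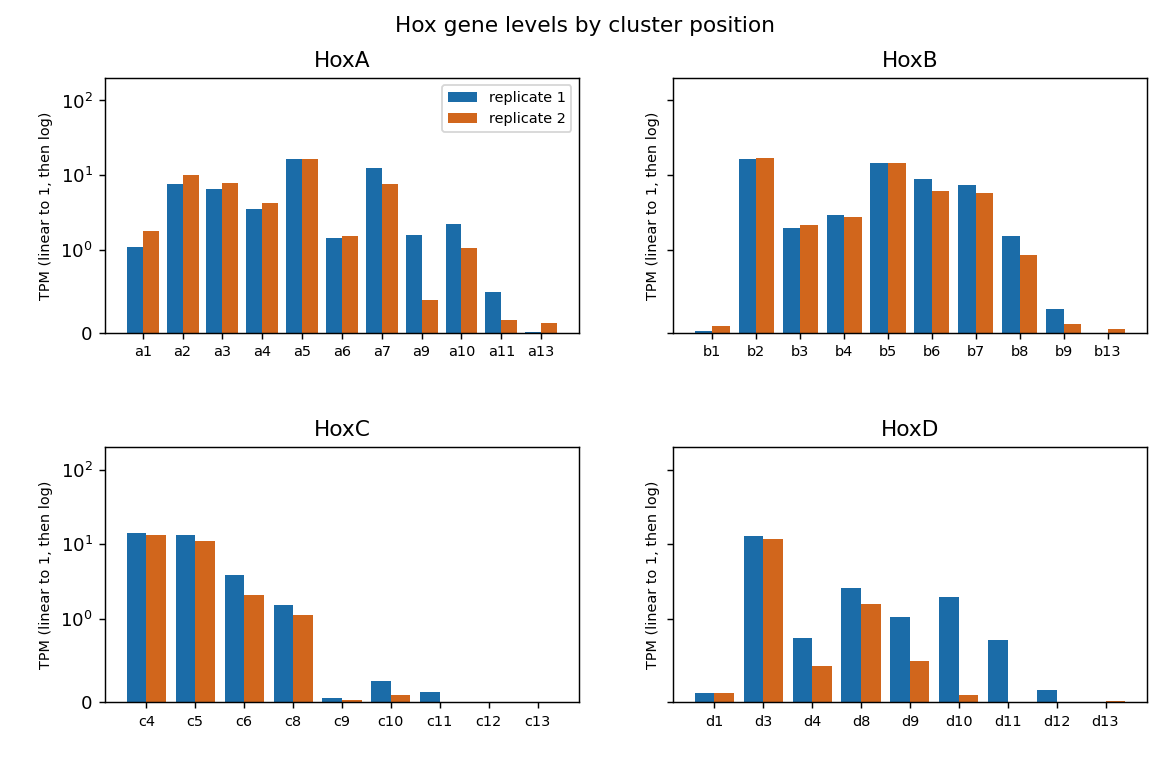
Levels of the Hox genes by position in each cluster, in TPM on an axis that is linear up to 1 and logarithmic above, for replicate 1 (blue) and replicate 2 (orange). Bars start at 0. Hoxd10 is at 2.0 TPM in replicate 1 and 0.08 TPM in replicate 2.

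Compared with replicate 1, genes of squamous epithelium, liver and red cells were lower in replicate 2, and genes of pancreas and striated muscle were higher. Smooth muscle, matrix and enteric nerve genes stayed inside the range of matched random lists, though matrix genes moved outside it with whole-count members alone. The median forestomach gene was lower in replicate 2 by a log2 ratio of -0.73, the median liver gene by -1.47 and the median erythroid gene by -0.87. The median exocrine pancreas gene was higher by 0.47 and the median striated muscle gene by 0.64. These ratios are relative to the median gene, because spike-in sizes alone moved the log2 ratios of all genes by -0.68.

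Forestomach genes were lower in replicate 2 for 13 of 13 members, and 5 were called different, namely Sprr3 (-2.09), Krtdap (-1.32), Krt4 (-1.31), Krt6a (-1.03) and Krt13 (-1.02). The list median lay below all 10000 random lists matched on expression. The edgeR exact test took its dispersion from the same 2 libraries, so the differences it tested are part of the spread they were set against, and its calls describe which genes stand out from the typical difference between the pools. With it, Sprr3, Krtdap and Krt4 kept their call (adjusted p = 9.87e-05, 0.0476 and 0.0449), and Krt6a and Krt13 lost it (0.247 and 0.259). Trp63 differed by -0.52 and Sox2 by -0.31, short of the 2-fold limit for a call. Gastric mucous genes had a median of -0.46, with Psca (-2.07), Gkn1 (-1.76) and Gkn2 (-1.07) called lower and Muc5ac (1.21) called higher. With the edgeR exact test Psca and Gkn1 kept their call and Gkn2 and Muc5ac lost it (adjusted p = 0.516 and 0.11). Among chief cell genes Gif (-1.51) and Pga5 (-1.12) were called lower (median -0.81 over 4 members). As means over members both the mucous and the chief list lay inside the central 95% of random lists. Atp4a (-1.12) was the only parietal gene called. The parietal list median was -0.07, and with whole-count members alone the list moved outside the central 95% on the low side. The edgeR exact test gave an adjusted p of 0.0422 for Gif, 0.157 for Pga5 and 0.175 for Atp4a. Chosen after their values were seen, the genes with the lowest ratios among those with whole counts included Crct1 (-2.95), Rptn (-2.36) and Cnfn (-2.02), with adjusted p of 2.75e-07, 1.95e-05 and 0.000172 by the edgeR exact test.

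Liver genes were called lower for 10 of 12 members, from Afp (-1.33) to Ahsg (-1.84), whereas Cps1 (0.75) and Apob (0.36) went the other way without a call. The edgeR exact test kept all 10 calls, with adjusted p from 0.000854 for Ahsg to 0.04 for Afp. Erythroid genes were lower for 12 of 13 members, and 5 were called, among them Klf1 (-1.46), Gata1 (-1.38), Slc4a1 (-1.15) and Hba-a1 (-1.02). The edgeR exact test kept Klf1 and Gata1 (adjusted p = 0.0187 and 0.0421) and lost the others, with 0.121 for Slc4a1 and 0.259 for Hba-a1. The embryonic globin Hbb-y, made by the first wave of red cells, had a ratio of 0.49. The other embryonic globins of the list, Hba-x (-0.02) and Hbb-bh1 (-0.23), were not higher. Exocrine pancreas genes were higher for 11 of 11 members with none called, and endocrine pancreas genes for 7 of 7 (median 0.24). In the striated muscle list Myh3 (1.90), Myog (1.69), Acta1 (1.33) and Tnnt3 (1.32) were called higher, and the edgeR exact test lost Tnnt3 (adjusted p = 0.0832). Gut endocrine (0.23), intestinal (0.19) and Notch pathway genes (0.13) were also above the central 95% of matched random lists. With whole-count members alone the gut endocrine list (0.15) was not. Of the gut endocrine members 9 were higher and 5 lower, and whether pancreas cells in the pools contributed was not tested. Spike-in sizes lower every gene alike. With them, the medians of these 3 lists, of both pancreas lists and of striated muscle lay between -0.55 and -0.034. All were above the shift of -0.68 of all genes. Sis (-1.98, adjusted p = 0.11 by the edgeR exact test, which lost the call) was called lower although the intestinal median was higher, and the mean over intestinal members was -0.057.

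Other lists differed by less. Mesothelial genes were lower for 8 of 8 members (median -0.16), Wnt pathway genes for 14 of 16 (-0.24), macrophage genes for 10 of 12 (-0.15), immediate early genes for 14 of 15 (-0.16, Hspa1b called at -1.44, a call the edgeR exact test lost) and structured noncoding RNAs for 7 of 7 (-0.21). BMP pathway genes (-0.11), mitochondrially encoded genes (-0.10, with mt-Nd4l called higher at 1.01, a call the edgeR exact test lost) and replication-dependent histones (-0.34, with 5 called lower, of which Hist1h2aj and Hist2h3c1 kept their call with the edgeR exact test) were also outside the central 95% of random lists on the low side. As means over members, the mesothelial, Wnt, macrophage, immediate early, noncoding RNA, BMP (-0.069) and mitochondrial (-0.069) lists lay inside it. BMP genes lay inside it also with TPM and FPKM, and mitochondrial genes also with whole-count members. Among lists inside it were smooth muscle (-0.01), enteric neurons and glia (-0.02), fibroblast and matrix genes (-0.04) and endothelium (0.04). So were glandular epithelium (0.07), mesenchyme (0.07), interstitial cells of Cajal (0.13) and lymphoid genes (0.39, with Rag1 called lower). The edgeR exact test lost the Rag1 call. Cell cycle (0.02), hedgehog (0.02), retinoic acid and FGF (-0.07), imprinted (-0.02), hypoxia (0.07) and sex-linked genes (-0.13) lay inside it too. Polyadenylated histone variants (0.06), housekeeping (0.11) and ribosomal protein genes (0.01) did as well. Mesenchyme lay outside it as a mean and with whole-count members, and matrix genes with whole-count members. Retinoic acid and FGF and housekeeping lay outside it with TPM and FPKM. In the sex-linked list Xist (0.22) and Tsix (0.02) were higher. Its Y-linked genes Eif2s3y (-0.19), Ddx3y (-0.16), Uty (-0.10) and Kdm5d (-0.43) were lower.

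The 6 HoxD genes with at least 20 counts in the sum were lower in replicate 2. Their median log2 ratio was -1.11, also with Hoxd11 set at its floor of 3 counts. In the whole cluster 5 genes were called lower, all at 2.0 TPM or less in both libraries. The 2 genes detected in both libraries, Hoxd3 (-0.14) and Hoxd8 (-0.77), were not called. Hoxd10 had 106 counts in replicate 1 and 4 in replicate 2 (-4.60), Hoxd11 58.03 and 0 (at least 19.9-fold lower), and Hoxd12 11 and 0 (at least 3.78-fold lower). Hoxd9 (-1.14) and Hoxd4 (-1.08) were called too. In the HoxA cluster Hoxa11 (-1.86), Hoxa9 (-1.33) and Hoxa10 (-1.11) were called lower, while the list median was 0.03. The HoxB (-0.27) and HoxC (-0.46) medians lay inside the central 95%, but HoxB moved outside it with whole-count members and HoxC with spike-in sizes. The edgeR exact test kept Hoxd10 and Hoxd11 (adjusted p = 7.71e-09 and 3e-08) and lost the others, with an adjusted p of 0.0671 for Hoxd12, 0.516 for Hoxd9, 0.811 for Hoxd4, 0.145 for Hoxa11, 0.238 for Hoxa9 and 0.349 for Hoxa10.

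**Figure D3:**
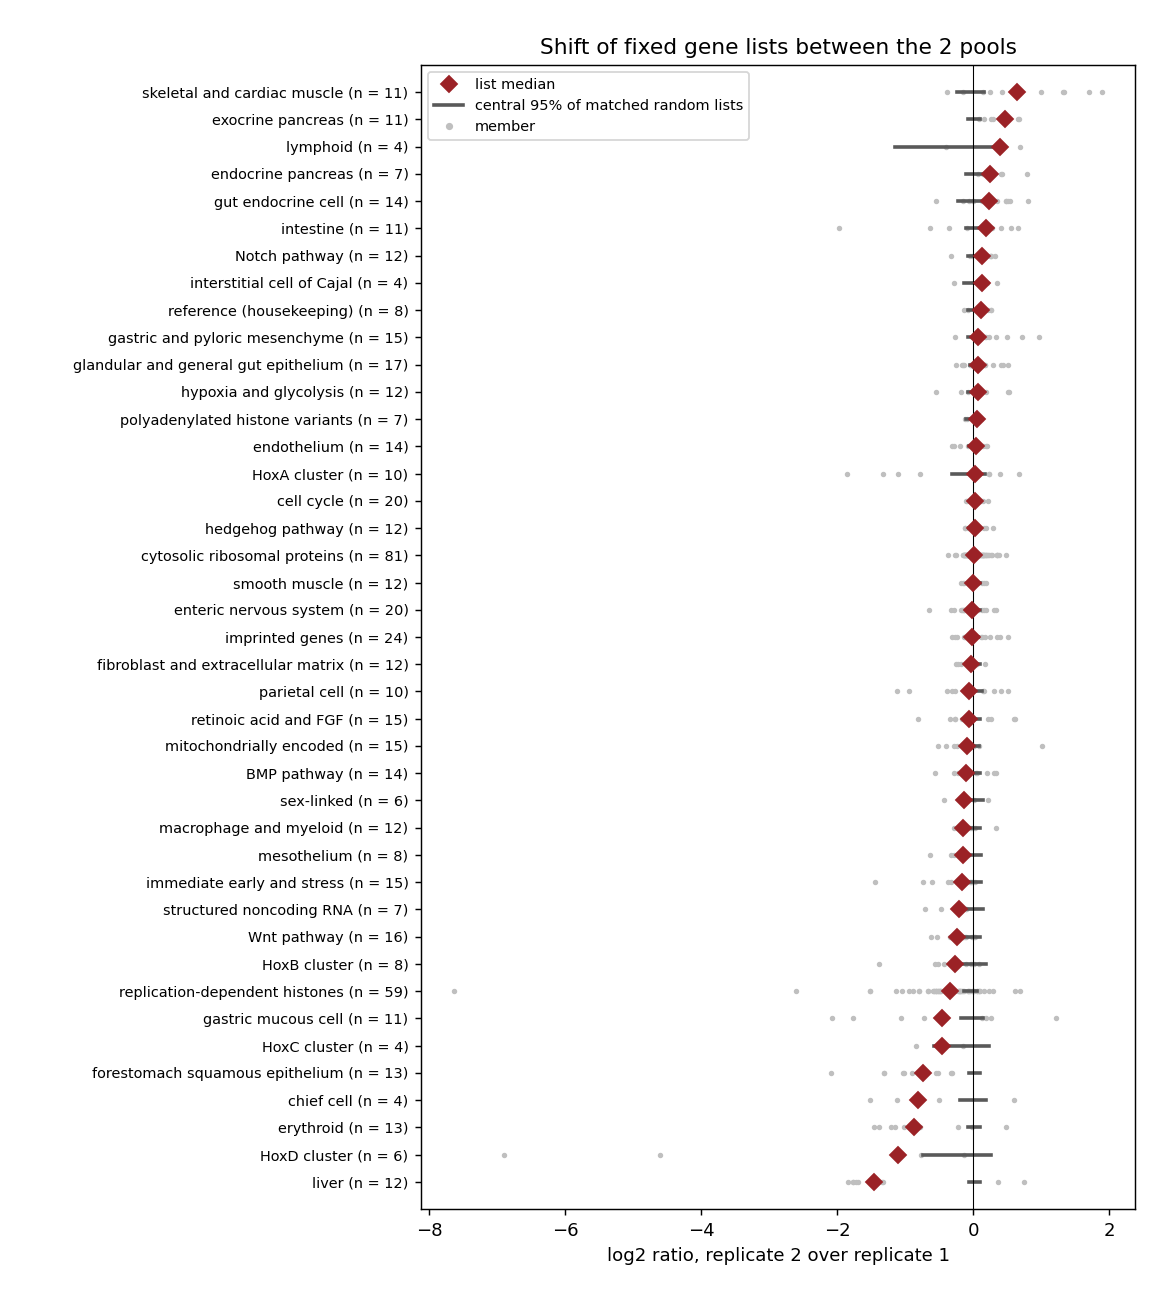
Log2 ratio of replicate 2 over replicate 1 for the fixed gene lists, with TMM library sizes. Red diamonds are list medians, grey points are members and dark bars are the central 95% of 10000 matched random lists. The liver median lies at -1.47 and the striated muscle median at 0.64, and with spike-in sizes, which move all genes by -0.68, the 6 higher lists outside the bars have medians below 0.

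Of 20918 genes tested, 1353 were called different by the exact binomial test (Benjamini-Hochberg), 164 higher and 1189 lower in replicate 2. The test compares these libraries, not conditions, and covers counting error only. The imbalance of higher and lower calls depended on the setting, and it was smaller without the minimum ratio or with whole counts only. The edgeR exact test called 687, of which 45 were higher and 642 lower. For each of the 46 lists, the count adjusted over the list alone equalled that over all genes tested. Among genes averaging at least 100 counts, the highest ratios belonged to the striated muscle genes Myh3 (1.90, 95% counting interval 1.64 to 2.17), Atp2a1 (1.70), Actn2 (1.67), Acta1 and Tnnt3, to the alcohol dehydrogenase gene Adh1 (33.68 and 106.33 TPM, 1.62), to the pseudogene 9130208D14Rik (1.46) and to the phosphate transporter gene Slc34a2 (1.33, adjusted p = 0.0641 by the edgeR exact test). The counts of Myh3, Atp2a1 and 9130208D14Rik were not whole, so part of their reads were shared with other genes. The lowest belonged to genes that share reads and are uncertain. Gm10273 had 1569.04 counts in replicate 1 and 0 in replicate 2 (at least 539-fold lower), Gm15725 had 425.11 and 0 (at least 146-fold lower) and Gm20425 had 319.83 and 0 (at least 110-fold lower). Rpl18-ps2 (-4.30), Gm9923 (-4.25), Rpl21-ps8 (-3.97), Amd-ps3 (-3.80) and Gm15772 (-3.78), all processed pseudogenes, followed. Processed pseudogenes made up 681 of the called genes, 674 of them lower, and protein-coding genes 488 (105 higher and 383 lower). Called or not, 1142 of the 1304 processed pseudogenes tested were lower in replicate 2.

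Across genes the libraries had a Pearson r of 0.978 and a Spearman rho of 0.981 on log2 values, where genes are not independent replicates. Of 15799 genes with at least 100 counts 93.3% lay within 1.5-fold. The chi-square of the counts was 27.1 per degree of freedom, so the tables do not hold a single library deposited again. The labels give the libraries as separate pools. The biological coefficient of variation was 19.7%, an estimate that genes differing between the libraries raise. Spike-in RNAs were higher in replicate 2 for 60 of 64 sequences, with a median log2 ratio of 0.66. The total spike-in count of replicate 2 was 1.65 times that of replicate 1, against 1.02 for the total gene count.

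Transcript usage was compared for 81 genes of the tissue lists. The leading transcript was the same in both libraries for 71 (87.7%). The largest changes of its share of gene TPM were in Onecut2 (67.6% in replicate 1 and 3.86% in replicate 2), Muc6 (62.5% and 0%), Muc5ac (91.8% and 64.5%), Foxa2 (96.2% and 75.0%) and Kcnj15 (35.4% and 18.0%). These shares are estimates from reads that transcripts of a gene have in common.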

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

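The tests of shared reads among the enzyme genes, of a few genes taking most of the counts and of greater depth were chosen after the result was seen. Features with numeric IDs, which no comparison used, carried 86 counts in replicate 1 and 85 in replicate 2, above the 3 counts that a count of 0 allows. Of these features 14 had counts, and a single one of 255 bases held 65 and 64.

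Digestive enzyme genes of the pancreas were abundant in both libraries. Of 9 enzyme genes 8 had whole counts, and these held 95.96% of the TPM of the 9 in the lower library, so reads divided among paralogs do not account for them, except for Prss1, whose trypsin paralogs had 218% of its counts in the lower library. The other acinar enzyme genes had a median of 11.8% of the Ctrb1 level in the lower library and 11.9% in the other, and the endocrine pancreas list had a median of 33.9 TPM in the lower library. Both values are what pancreas tissue in the dissected pools would give, and a candidate explanation is that some pancreas was taken with the stomach. The design has a single group and gives no biological explanation to test. For this and the next 2 patterns only tissue in the dissected pools and technical sources were weighed.

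Liver and red cell genes were lower in replicate 2. The 10 most abundant genes took 4.97% and 4.53% of the counts, which argues against a few genes taking most of the counts. Less liver in the pool of replicate 2 was tested on 19 liver genes outside the fixed list, picked once the result of that list was known: 16 of the 17 with enough counts were lower, with a median log2 ratio of -1.19 (-1.35 to -0.89), and because the interval passes the bound of -1 set for it, less liver stays open. This test took the place of 2 earlier ones, the fixed liver list without Alb and with globin genes left out of the totals, which had little chance of coming out otherwise and are not used. Less liver may also bear on the red cell genes, since the liver makes red cells at this stage, but that was not tested.

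Of 1304 processed pseudogenes tested, 674 were called lower in replicate 2 and 7 higher. The shift was not limited to the called ones: 1142 of those tested were lower, with a median log2 ratio of -1.54. The class held 1.16% of the gene counts in replicate 1 and 0.744% in replicate 2. Greater depth of replicate 1 is excluded, since the gene count of replicate 2 was 1.02 times that of replicate 1. Genomic DNA in replicate 1 is argued against by the olfactory and vomeronasal receptor genes, whose count per library size in replicate 1 was 0.872 times that in replicate 2 (0.711 to 1.06). Reads of expressed parent genes placed on their copies stay open: 74.8% of the called pseudogenes had a parent at 100 TPM or more, between the bounds of 50% and 80% set for this test, against 70.4% of the others. The counts of 97.6% of the called pseudogenes were not whole, against 75.8% of the rest, while their parents had a median log2 ratio of 0.03.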

How the results depend on the processing

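Restrictions to whole counts and to protein-coding genes, and the forestomach ratio without 3 members, were chosen after the result was seen. No paired analysis was possible because there is a single group, and results that compare the libraries have no version with a library left out. Where a value changed, the cause was not tested unless the setting itself shows it. Counts of detected genes stayed within 1.5 times. Genes with the same leading transcript made up 89.4% at 500 counts or more and 92.6% with expected-count shares, while the median change of the leading share went from 3.37 to 1.92 and 1.56 percentage points. Expected-count shares moved the 5 largest isoform changes by less than 1.5 times, and Muc6, Muc5ac and Kcnj15 fell short of 500 counts. The 22 ratios of other tissues to silent controls kept their sign in 153 of 154 alternatives, but 90 of these moved by more than the SD of both libraries. For single named genes, 105 log2 ratios under other settings stayed within their counting interval and 7 did not.

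List level percentiles crossed the central 95% as follows. With CPM, interstitial cells of Cajal moved to 97.6, retinoic acid and FGF to 96.4, structured noncoding RNA to 78.0 and replication-dependent histones, which are short, to 1.36. With members of at least 10 counts only, endocrine pancreas moved to 99.5, retina and lens controls to 9.93, germ line controls to 6.0 and mitochondrially encoded genes, whose tRNAs are then left out, to 100. With posterior-mean TPM the lymphoid list moved to 2.33. Without replicate 1 or replicate 2, liver ranged from 93.9 to 99.7 and retinoic acid and FGF from 97.45 to 98.7.

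Ratios of list medians depended on the unit. With CPM, forestomach to glandular epithelium was -0.055, glandular epithelium to mesenchyme 0.57, mucous, parietal and chief to endocrine genes 1.64, 1.62 and 1.99, and histone classes -8.17. Without the 3 highest members forestomach to glandular was 0.27, and chief to endocrine was 1.80 with members of at least 10 counts. Without a library, the forestomach ratio ranged from 1.06 to 2.32, the mucous ratio from -1.15 to -0.13 and the glandular to mesenchyme ratio from 0.032 to 0.17, and the parietal ratio, from -0.33 to 0.20, changed sign.

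The biological coefficient of variation was 19.4% with DESeq2 size factors, 19.1% with library totals, 20.2% with no filter and 17.2% at 100 counts or more. Calls higher and lower were 37 and 531 at 100 counts or more, 3149 and 3439 with no minimum ratio, 45 and 642 with the edgeR exact test, 89 and 316 with whole counts only, and 105 and 389 with protein-coding genes only.

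List shifts changed their side of the bound as follows. As means over members, mucous (-0.47), chief (-0.63), mesothelium (-0.23), macrophage (-0.10), Wnt (-0.23), BMP (-0.069), immediate early (-0.31), structured noncoding RNA (-0.29) and mitochondrial genes (-0.069) moved inside, intestine (-0.057) changed sign and mesenchyme (0.20) moved outside. With TPM, BMP (-0.076) moved inside and retinoic acid and FGF (-0.067) and housekeeping (0.16) outside, and with FPKM likewise (-0.11, -0.11 and 0.12). Spike-in sizes turned gut endocrine (-0.45), lymphoid (-0.28), exocrine pancreas (-0.21), endocrine pancreas (-0.44), intestine (-0.49), striated muscle (-0.034) and Notch (-0.55) negative, because they moved all genes by -0.68, and put HoxC (-1.14) outside. With whole-count members, gut endocrine (0.15) and mitochondrial genes (-0.063) moved inside and parietal (-0.27), mesenchyme (0.12), matrix (-0.076) and HoxB (-0.47) outside. All other list shifts kept their side of the bound, but medians inside it changed sign in 11 cases with spike-in sizes and in 14 cases, from 9 lists, with other settings, among them HoxA (-0.35 as a mean). Depth limits statements on genes with few counts, such as Hoxd12.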

Other observations

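The tests below were written before their results were seen, apart from the comparison of genes with whole counts, which was chosen after the result was seen. Among the genes with the lowest ratios there, Crct1 was at 18.58 TPM in replicate 1 and 2.45 TPM in replicate 2, Cnfn at 340.17 and 86.26, Asprv1 at 86.21 and 25.48, Klk10 at 14.4 and 3.42, Serpinb3a at 5.28 and 1.28 and Rptn at 4.95 and 0.99, with adjusted p from 2.75e-07 for Crct1 to 0.00123 for Asprv1 by the edgeR exact test. These 6 were picked after their values were seen, and no test of a shared function was made. The muscle genes Ttn (1.13), Neb (1.11) and Mybpc1 (1.06) were called higher on the log2 scale by the exact binomial test, and none of these 3 was called by the edgeR exact test (adjusted p = 0.161, 0.246 and 0.291).

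Forestomach squamous genes were lower in replicate 2, as were the medians of the mucous (-0.46) and chief cell lists (-0.81), and a slightly earlier stage of its embryos might give that. Muc5ac was higher (1.21), and as means the mucous and chief shifts lay inside the central 95% of random lists. Genes that fall with embryonic age in many tissues (Lin28a, Lin28b, Hmga2, Igf2bp1, Igf2bp2, Igf2bp3, Trim71 and Mycn) had a median log2 ratio of 0.095 (-0.041 to 0.14), with 6 of 8 higher. The whole range lies below the 0.3 set for an earlier stage, so these 8 genes as a set did not move that far. A stage difference stays open, because the range includes the bound of 0.1 set against it. The range was taken over genes and not over pools, and how far these genes move with stage in the stomach was not measured.

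Of the HoxD genes 5 were called lower in replicate 2 by the exact binomial test, Hoxd10 and Hoxd11 also by the edgeR exact test, and Hoxa9, Hoxa10 and Hoxa11 were called lower by the exact binomial test alone. Kidney tissue in the pool of replicate 1 was tested as a possible source. Of 13 kidney markers 6 had enough counts, and their median log2 ratio was -0.030 (-0.59 to 0.43), while Umod, Slc12a1 and Aqp2 had 0 counts in both libraries. The intervals in this test and the stage test were added after the medians were seen; by the medians alone both explanations had first been read as excluded. The whole range lies above the -1 set for kidney tissue as the cause, so these 6 markers as a set did not move that far. Kidney tissue stays open, because the range of so few markers includes the bound of -0.3 set against it. The range was taken over markers and not over pools, and other tissues that express these markers were not accounted for.

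The median of replication-dependent histones was 1.78% of that of polyadenylated variants in replicate 1 and 1.10% in replicate 2. Summed over members, the replication-dependent class held 4688.65 and 3866.65 TPM against 5099.51 and 5486.03 TPM for the variants. These percentages therefore do not describe totals. A comparison set up to tell whether the libraries came from poly(A) RNA alone had bounds of 1% and 10%. Both percentages fell between them, so it decided nothing. It was dropped from the set of weighed tests after these values were seen.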
